A study of Arabidopsis thaliana with 2 samples.

How the data were processed

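Gene expression was measured in inflorescence stems of Arabidopsis thaliana wild type (Columbia) and sgr1 on 2 Agilent two-colour arrays, both on 1 slide. Per the labels, plants were grown under constant light at 23 °C, each RNA sample came from at least 10 plants with stems 5 to 8 cm tall, and 500 ng of total RNA entered each labelling. The labels call the arrays 2 biological replicates in one place and replicate 1 of 1 in another, and state that every cRNA was labelled with both dyes. The arrays were therefore treated as 2 replicates, with their mean as 1 replicate among the alternatives.

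The deposited scanner files hold, per spot, the mean intensity of the spot and the median intensity of its local background in each channel, together with processed intensities, per the file headers from Agilent Feature Extraction 9.1.3.1. They also hold a log10 ratio of Cy5 over Cy3 after the software's own background subtraction and dye normalization, per the file headers. The deposited value table of the series holds the same log10 ratio, since none of its 39102 values per array differed from it by over 1e-06; it is not turned for the dye swap, both of its columns have a median of 0, and 24.5% and 24.8% of the values are exactly 0. The genome build behind the probes is not given in the sources used here.

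Mean and background intensities were corrected with normexp (offset 50) and normalized within each array by loess, with control spots and outlier spots at weight 0, in limma 3.58.1 under R 4.3.3. No scaling between arrays was applied. The log2 ratio of array 1 was turned in sign so that both arrays read sgr1 over wild type, and a dye effect then cancels in the mean. Outlier spots (96 on array 1 and 177 on array 2) were left out. Probes were kept where at least 1 channel was well above background on each array, and the kept probes of a gene were averaged. This left 19059 genes of the 25665 loci named on the array. Of these, 422 had several probes, and in 1 gene the probes differed by over 1 log2 unit. The 11251 spots that name no locus were left out of the comparison. After normalization the median log2 ratio of the kept genes was -0.03 on array 1 and 0.04 on array 2.

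Each gene's ratio was tested against 0 with limma (lmFit and eBayes, two-sided, Benjamini-Hochberg adjustment, threshold 0.05), with 1 residual degree of freedom per gene and 48.3 prior degrees of freedom shared across genes. A gene can thus be called although its arrays differ, since its spread is drawn towards that of all genes (prior SD 0.198). Gene lists with at least 5 measured members were tested with camera (preset inter-gene correlation 0.01). The 21 lists, the tests, the rule for named genes and the alternatives were chosen before the data were examined, apart from those named otherwise.

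The named genes were SCR, the called members of the endodermis and gravitropism lists, up to 4 called members of each other list with the largest changes, and the 12 higher and 12 lower called genes with the largest mean change among those at least 2-fold apart on both arrays. Loci without a symbol were skipped in that last group, 6 higher and 10 lower, among them LZY1, whose name comes from the gravitropism list. Where a count of 5 or fewer called members of a list held genes outside this rule, they were named too, having been chosen after their values were seen, as were the uncalled members given by value. Symbols came from a table of the TAIR10.1 assembly, used for names and gene order only; 18949 of the 19059 genes matched it. List members carry the names under which the lists were written, by locus.

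In 77 genes sgr1, and in 35 genes wild type, was well above background on neither array. For such genes a fold is given as a lower limit, the mean of the brighter genotype against the higher of the dim signal and the lowest signal well above background, per channel after loess and Aquantile normalization.

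The procedure was tested on simulated data in which some of the 19059 genes of the comparison were changed by known folds under a brightness-dependent dye bias. Of the genes changed 1.5-fold, 53.7% of 67 were called in the right direction, of those changed 2-fold 94.0% of 67 and of those changed 4-fold 100% of 66, and 2 of the 167 calls were unchanged genes. Only these 67, 67 and 66 genes were changed, far fewer than the 3607 called in the data, and every gene had the same random spread. The shares called and the 2 false calls hold for that setting and may differ in the data. The genes missed at 2-fold were dim. Among genes below the 25th percentile of brightness 71.4% of 14 were called at 2-fold, and 61.4% of the true log2 change was recovered, against 97.9% in genes above the 50th percentile. Changes of dim genes are therefore understated.

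Alternatives covered the background correction (normexp offset 16, or none), the normalization within arrays (median centring) and between arrays (Aquantile, scale), the starting values (the software's log ratio and the series table), the filter on dim probes (none, or both channels), the brightest probe per gene, eBayes with trend and robust, each array alone, the averaged arrays, camera with an estimated correlation, fry, and a threshold with a size rule. A test against 1.5-fold (limma treat) and a comparison with 10000 random lists matched in 20 bins of brightness were added after the data were seen.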

Results

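The data comprised 2 two-colour Agilent arrays that compared inflorescence stems of Arabidopsis thaliana wild type (Columbia) with those of sgr1. The sgr1 (shoot gravitropism 1) mutant carries a lesion in SCARECROW (SCR), which encodes a GRAS transcription factor required to form the endodermis, the cell layer that holds the sedimenting starch plastids of the shoot. RNA came from stem segments 1.5 cm long, cut 0.3 to 1.8 cm below the apex and stripped of lateral organs. Each array carried both genotypes. In array 1 sgr1 was labelled with Cy3 and wild type with Cy5, and in array 2 the dyes were swapped. Between 59.2% and 66.5% of the non-control spots were well above background in each of the 4 channels, and no spot was saturated. Values below are log2 ratios of sgr1 over wild type, given as the mean ± SD of the arrays (n = 2), and folds are those of the mean. Adjusted p-values come from limma with Benjamini-Hochberg adjustment. The labels differ on whether the arrays hold separate biological samples. P-values of single genes thus rest on the spread between these arrays, pooled across genes, which may be technical. P-values of lists by camera with the preset correlation compare list members with the other genes. They do not measure the spread between arrays.

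SCR itself was 1.98-fold lower in sgr1, with log2 ratios of -0.81 on array 1 and -1.16 on array 2 (AT3G54220, adjusted p = 3.13e-07). The allele is not given in the sources used here, so its probe may lie outside the lesion, in which case it does not check the genotype labels. The strongest change in either direction was a rise of PER64 (AT5G42180), a peroxidase that acts in lignification of the root Casparian strip, which was 18.5-fold higher in sgr1 (4.21 ± 0.0636). The strongest fall was that of ARD3 (AT2G26400), an enzyme of the methionine salvage cycle, which was 16.9-fold lower (-4.08 ± 0.363). Among the genes with a known role in shoot gravitropism, LZY1 (AT5G14090), which links plastid sedimentation to auxin transport, was 4.44-fold lower (-2.15 ± 0.178).

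Of 19059 genes tested, 3607 were called at an adjusted p under 0.05, 1894 higher and 1713 lower in sgr1. The smallest called change was 0.37 on the log2 scale. A rule of size that needs no replicate, at least 2-fold in the same direction on both arrays, held for 291 genes, 148 higher and 143 lower. Only 1 gene was at least 2-fold apart on both arrays in opposite directions. That is a background for dye effects and noise of the arrays alone. If both arrays carry the same extracts, a difference between plant pools unrelated to genotype has the same sign on both and is not covered. Across genes, which are not independent replicates, the ratios of the arrays correlated with r = 0.72. Other settings moved these counts by over 1.5 times. Median centring in place of the loess normalization left 2 calls and 115 genes at least 2-fold apart on both arrays, and it ended the call of SCR (-0.98). The log ratios computed by the scanner software gave 1952 calls and 705 such genes. With trend and robust eBayes the balance of calls turned to 1534 higher and 1777 lower.

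**Figure D1:**
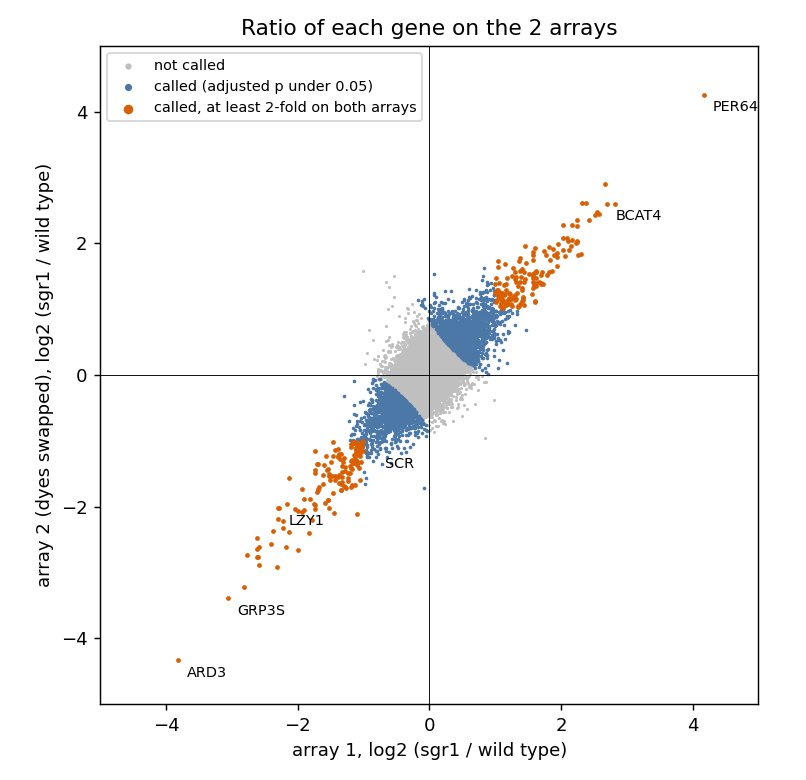
Log2 ratio of sgr1 over wild type on array 1 (horizontal axis) and on array 2, whose dyes were swapped (vertical axis); each point is 1 of the 19059 genes tested. Orange points are the 291 genes called and at least 2-fold apart in the same direction on both arrays, blue points the other called genes and grey points those not called.

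The 12 named genes with the largest rises included 4 of the fixed list for synthesis of glucosinolates, defence compounds of the cabbage family. These were BCAT4 (2.65 ± 0.0654) and MAM1 (2.51 ± 0.058), which lengthen the methionine side chain, SOT17 (4.92-fold higher, SD 0.0838), which adds the sulfate group, and FMO GS-OX1 (2.11 ± 0.0864), which oxidises the side chain. The others, besides PER64, were AK3, an aspartate kinase (2.47 ± 0.203), IPMI1, a subunit of isopropylmalate isomerase (2.16 ± 0.177), EXLB1, an expansin-like protein (2.79 ± 0.159), ABCB13, an ABC transporter (2.71 ± 0.149), CYP86A4, a fatty acid hydroxylase of cutin synthesis (2.23 ± 0.0846), MYB61, a transcription factor (2.13 ± 0.164), and RAB18, a dehydrin induced by abscisic acid (2.12 ± 0.151).

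Among the 12 named genes with the largest falls, besides ARD3, were GRP3S, a glycine-rich wall protein (-3.22 ± 0.239), ATPMEPCRB, a pectin methylesterase (-2.76 ± 0.0255), ADF9, an actin-binding protein (-2.69 ± 0.106), and EXT3, an extensin of the cell wall (-2.33 ± 0.461). PCC1 (-2.63 ± 0.0132), HR4 (-2.60 ± 0.0247) and the transcription factor WRKY53 (-2.26 ± 0.183) are induced by pathogens or salicylic acid. PRA1.F1, of a family of membrane trafficking proteins (-2.61 ± 0.43), MSRB9, a methionine sulfoxide reductase (-2.28 ± 0.0684), FTM1, an acyl carrier protein desaturase (-2.40 ± 0.313), and AT14A (-2.12 ± 0.399) completed the group. For FTM1 and AT14A the signal of sgr1 was well above background on only 1 array.

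Of 20 measured genes for endodermis identity and barrier, 2 rose and 5 fell, and adjusted over the list alone 3 rose and 5 fell. Besides SCR, the falls were those of EN7 (-0.66 ± 0.295), a marker of the layer, SNE (-0.55 ± 0.351), an F-box protein of gibberellin signalling, SHR (-0.53 ± 0.0884), the partner of SCR, and BLJ (-0.42 ± 0.0913), a zinc finger protein that acts with both. PER64 and SCL3 (0.43 ± 0.152), a GRAS protein, rose. The Casparian strip genes CASP1 (-0.04), CASP2 (0.06), CASP4 (0.14) and ESB1 (-0.11) did not pass the test. CASP1 was well above background on only 1 array in each genotype, and CASP4 on only 1 in wild type. Changes of these dim genes may be understated. As a group the list did not shift (camera adjusted p = 0.867), with a median of -0.04 and a mean of 0.10. With the scanner software's log ratios the calls of SNE, SHR, SCL3 and BLJ were lost.

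Of 16 measured shoot gravitropism genes, 2 rose and 3 fell, and adjusted over the list alone 2 rose and 4 fell. After LZY1, the falls were of SGR5 (-1.02 ± 0.043), a zinc finger protein of the endodermis, and LZY2, a relative of LZY1. LZY2 was not well above background in sgr1, so that it was at least 1.38-fold lower there. PGM1 (0.73 ± 0.274) and ADG1 (0.38 ± 0.161), enzymes of starch synthesis, rose. The rise of ADG1 was close to the threshold (adjusted p = 0.0467) and was lost with 8 of the other settings. SGR2 (-0.02), VTI11 (0.26), SGR9 (-0.29) and the auxin carrier gene PIN3 (-0.10) did not pass. The list as a whole did not shift (camera adjusted p = 0.0827, median -0.07), although it passed with a normexp offset of 16 (adjusted p = 0.0293) and with median centring (adjusted p = 0.0327).

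**Figure D2:**
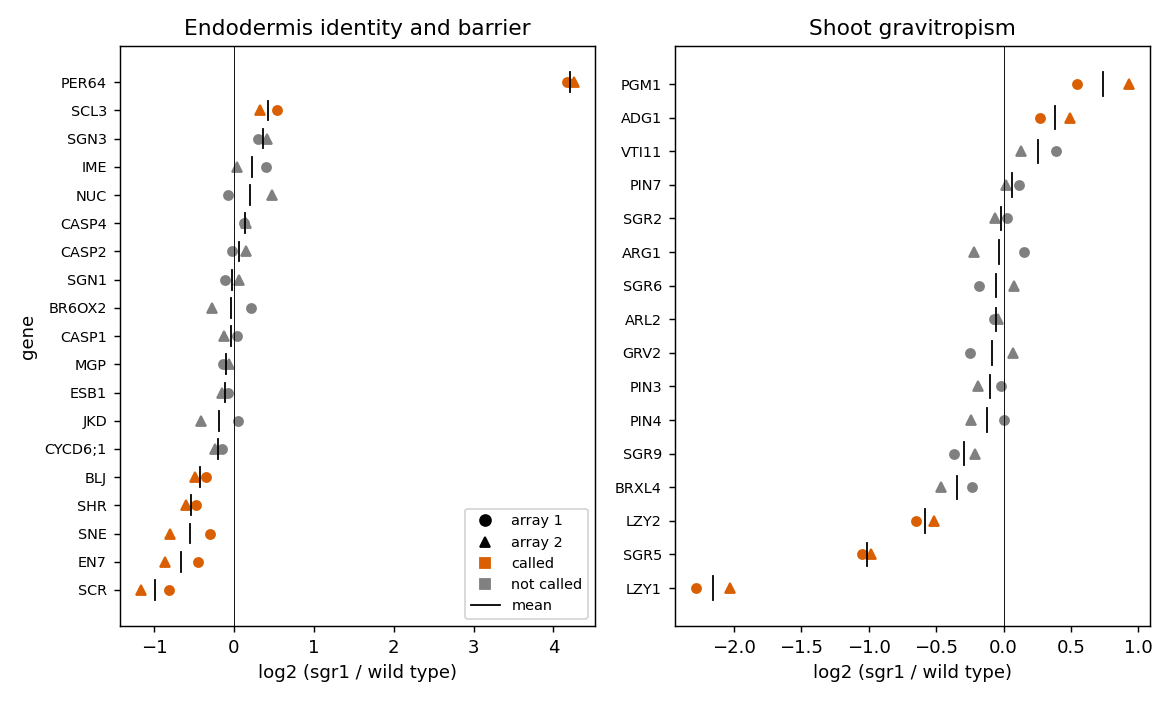
Log2 ratio of sgr1 over wild type for all but 1 of the 20 measured endodermis genes (left) and the 16 measured shoot gravitropism genes (right), with array 1 as circles, array 2 as triangles and the mean as a black bar. Orange marks the called genes, which reach from -2.15 for LZY1 to 4.21 for PER64.

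Tested as groups with camera, 11 of the 21 gene lists shifted, 7 towards higher and 4 towards lower values in sgr1. With an inter-gene correlation estimated from the arrays, which leaves 1 residual degree of freedom, no list passed. None passed with fry either, a test of movement one way that also rests on 1 residual degree of freedom. That 1 degree of freedom leaves camera almost no power: the glucosinolate list had adjusted p = 3.09e-17 with the preset correlation and 0.616 with the estimated one. Adjusted p-values with an estimated correlation below therefore say little about any list. The estimates exceeded the preset 0.01 for photosynthesis (0.37), pathogen (0.29), starch (0.17), wounding (0.12), cuticle (0.07), wall expansion (0.04) and stomatal genes (0.03). They lay below it for glucosinolate (-0.07), flavonoid (-0.07), secondary wall (-0.02) and cell cycle genes (-0.02). Where members vary together more than the preset allows, its p-values are too small. By fry's test of change in either direction 4 lists passed. As a description of these arrays, the medians of 11 lists lay outside the central 95% of 10000 random lists of matched brightness. These were not the same 11 lists: the wounding list, which passed with camera, lay inside (percentile 4.19), and the auxin response list, which did not pass, lay outside (percentile 99.98).

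Genes for glucosinolate synthesis showed the largest shift. Of 15 measured, 11 rose and 1 fell, with the same counts adjusted over the list alone, and their median was 2.18-fold higher in sgr1 (camera adjusted p = 3.09e-17, and adjusted p = 0.616 with an estimated correlation). BCAT4, MAM1, SOT17 and FMO GS-OX1 led the list. The gene that fell was CYP83B1 (-0.66), of the tryptophan-derived indolic branch.

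Of 15 measured flavonoid genes, 10 rose and 2 fell, and adjusted over the list alone 12 rose and 2 fell. The median was 1.48-fold higher (camera adjusted p = 7.91e-07, and adjusted p = 0.616 with an estimated correlation). TT7, the flavonoid hydroxylase entered in the list as F3PRIMEH, rose most (1.54 ± 0.181), followed by MYB75, an activator of anthocyanin synthesis (1.19 ± 0.218), and F3H, an early enzyme of the pathway (1.00 ± 0.238). MYB11, an activator of flavonol synthesis, was not well above background in wild type and was at least 1.80-fold higher in sgr1. The falls were of TT8 (-0.55) and UGT79B1, which act in the proanthocyanidin and anthocyanin branches. UGT79B1 was not well above background in sgr1 and was at least 1.38-fold lower there.

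Of 24 measured epidermis and cuticle genes, 16 rose and 1 fell, and adjusted over the list alone 17 rose and 1 fell. Their median was 1.50-fold higher (camera adjusted p = 5.2e-09, and adjusted p = 0.616 with an estimated correlation). CER1 (1.14 ± 0.383) and CER4 (1.06 ± 0.0598), which make wax alkanes and alcohols, CER2 (0.85 ± 0.0921), needed to elongate wax precursors, and the lipid exporter ABCG11 (0.93 ± 0.151) had the largest changes. PDF1, a marker of the protoderm, fell (-0.69).

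Of 12 measured stomatal lineage genes, 1 rose and 5 fell, with the same counts adjusted over the list alone (median -0.22, camera adjusted p = 0.0143, and adjusted p = 0.616 with an estimated correlation). EPF2, a peptide that limits stomatal number (-0.93 ± 0.253), POLAR (-0.82 ± 0.202) and BASL (-0.67), which polarise the precursor cell, the receptor TMM (-0.73 ± 0.269) and the transcription factor SPCH (-0.64) fell, and the receptor kinase ERL1 rose (0.93 ± 0.391). The description of the POLAR probe names WRKY18, the neighbouring gene, which also fell (-0.74), so which of them it measured is uncertain. The median of the stomatal list was -0.33 on array 1 and -0.22 on array 2. Cell cycle genes also shifted lower: of 32 measured none rose and 6 fell, and adjusted over the list alone 7 fell (median -0.23, camera adjusted p = 0.00167, and adjusted p = 0.616 with an estimated correlation). PCNA1, the replication clamp (-0.56 ± 0.147), CYCD3;1, a D-type cyclin (-0.52 ± 0.0993), CDKB2;1, a mitotic kinase (-0.42 ± 0.00171), and MCM5, a replication helicase subunit (-0.42 ± 0.0214), were among them, and these 4 calls were lost with the scanner software's log ratios.

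Of 32 measured starch genes, 13 rose and none fell, the same counts adjusted over the list alone (median 0.27, camera adjusted p = 0.00018, and adjusted p = 0.616 with an estimated correlation). The largest rises were those of the beta-amylases BAM5 (1.12 ± 0.343), BAM1 (1.08 ± 0.0844) and BAM3 (0.80 ± 0.0149). BAM1 and BAM3 degrade starch, while PGM1 acts in its synthesis. Of 20 wall expansion genes, 6 rose and 3 fell, and adjusted over the list alone 7 rose and 3 fell (median 0.16, camera adjusted p = 0.0192, and adjusted p = 0.616 with an estimated correlation). All 6 that rose were expansins, and the median of the list was 0.11 on array 1 and 0.27 on array 2. They were led by EXPA8 (2.06 ± 0.134), EXPA11 (1.65 ± 0.196) and EXPA10 (0.97 ± 0.0965), and the 3 that fell were the xyloglucan-modifying enzymes XTH22 (-1.08 ± 0.0982), XTH16 (-0.64) and XTH9 (-0.51).

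Of 39 measured genes of xylem and fibre secondary walls, 9 rose and 1 fell, and adjusted over the list alone 10 rose and 1 fell (median 0.21, camera adjusted p = 0.00167, and adjusted p = 0.616 with an estimated correlation). MYB61, NST1, a switch of fibre wall formation (0.78 ± 0.15), and PAL2, at the entry to lignin synthesis (0.55 ± 0.0672), rose. VND6, a switch of vessel formation, was called lower (-0.49 ± 0.621), but its ratio was -0.05 on array 1 and -0.92 on array 2. Photosynthesis genes were called 17 higher and 1 lower of 42, and adjusted over the list alone 24 higher and 1 lower (median 0.38, camera adjusted p = 2.9e-07, and adjusted p = 0.616 with an estimated correlation). The median was -0.0039 on array 1 and 0.84 on array 2, so the arrays did not show this shift alike. RBCS2B (1.23 ± 0.558) and RBCS3B (0.76 ± 0.35), small subunits of Rubisco, and LHCB3, a light-harvesting protein (0.72 ± 0.299), rose and LHCB1.4 fell (-1.40 ± 0.236). The RBCS and LHCB1 genes have near-identical copies that can hybridise to the same probe, so which copy changed is uncertain.

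Genes for wounding, touch and jasmonate shifted lower, with 2 rises and 6 falls among 20, and 3 rises and 6 falls adjusted over the list alone (median -0.10, camera adjusted p = 0.0109, and adjusted p = 0.616 with an estimated correlation). WRKY53, the calmodulin-like TCH3 (-1.49 ± 0.319) and XTH22 fell, and the jasmonate-induced storage proteins VSP2 (1.44 ± 0.0749) and VSP1 (0.45) rose. The median was -0.24 on array 1 and 0.012 on array 2, and with the scanner software's log ratios the list no longer passed (adjusted p = 0.0549), although its median was larger in size (-0.24). Pathogen response genes had 2 rises and 5 falls among 10, with the same counts adjusted over the list alone (median -0.36, camera adjusted p = 0.0381, and adjusted p = 0.682 with an estimated correlation). PR5 (-1.09 ± 0.0794), PR2, WRKY70 (-0.87 ± 0.108), PAD4 (-0.52 ± 0.268) and EDS1 (-0.46), which act in or respond to salicylic acid signalling, fell. PR2 was not well above background in sgr1 and was 1.50-fold lower there, the lower limit being equal to the plain fold. EDS5 (0.51), a carrier needed to make salicylic acid, and PAD3 (0.47), an enzyme of camalexin synthesis, rose. PR1, a marker of salicylic acid responses, did not pass (0.04). The median of the list was -0.38 on array 1 and -0.20 on array 2. The list no longer passed with the scanner software's log ratios (median -0.41, adjusted p = 0.125) or with both channels required above background (median -0.36, adjusted p = 0.0752), which kept its size. Without the filter on dim probes its median shrank to -0.0375 (adjusted p = 0.114).

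The remaining 8 lists did not shift by camera. Auxin response genes had 12 rises and 4 falls among 25, with the same counts adjusted over the list alone (median 0.23, camera adjusted p = 0.0728). SAUR20, of a growth-promoting family (0.91 ± 0.181), and GH3.5, an enzyme that conjugates auxin (0.86 ± 0.00763), rose, while the repressor IAA17 (-1.08 ± 0.0946), GH3.3 (-0.82 ± 0.0735), IAA5 (-0.71) and IAA30 (-0.67) fell. SAUR19 to SAUR24 are close copies, and probes may not separate them. Of 19 auxin transport genes 2 rose and none fell, the same adjusted over the list alone, namely the kinase PID (0.67 ± 0.158) and PILS5, an intracellular auxin carrier (0.57 ± 0.281), with a camera adjusted p of 0.466. Among 18 gibberellin genes 2 rose and 1 fell, also adjusted over the list alone. GASA6, which gibberellin induces (1.56 ± 0.249), and SCL3 rose and GA3OX1, a gibberellin synthesis enzyme, fell (-0.47 ± 0.247). Their median was -0.05 and the direction given by camera was higher (adjusted p = 0.814).

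Among 23 phloem and cambium genes 2 rose and 1 fell, the same adjusted over the list alone (median -0.06, mean 0.0061, camera adjusted p = 0.867). The sulfate carrier SULTR2;1 (1.36 ± 0.0686) and the sugar exporter SWEET12 (0.57 ± 0.527) rose and OPS, a protein of phloem differentiation, fell (-0.47 ± 0.258). Of 8 measured flower and shoot meristem genes 2 rose and none fell, and adjusted over the list alone 3 rose (camera adjusted p = 0.191). This list passed with a normexp offset of 16 (adjusted p = 0.0381) and with the scanner software's log ratios (adjusted p = 0.0482). AP1, a floral identity gene, rose (0.61 ± 0.187), and SEP1, another, was not well above background in wild type and was at least 1.54-fold higher in sgr1. Of 9 suberin genes KCS2, a fatty acid elongase, rose (0.44 ± 0.378), and adjusted over the list alone 3 rose and 2 fell (median -0.03, mean 0.05, camera adjusted p = 0.834). Of 6 heat shock genes HSFA2, a heat-induced transcription factor, fell (-0.40 ± 0.0331), also adjusted over the list alone (camera adjusted p = 0.534). Of 20 clock genes 4 rose and 3 fell, the same adjusted over the list alone (median -0.03, mean 0.0037, camera adjusted p = 0.979). RVE1 (0.67 ± 0.3), RVE8 (0.63 ± 0.451), LNK1 (0.52) and CCA1 (0.38) rose, and ELF4 (-0.86 ± 0.172), CHE (-0.68 ± 0.0851) and GRP8 (-0.44) fell. Among the genes named from the lists, the calls of GA3OX1, PAL2, VND6, OPS, KCS2, PAD4 and RVE8 were also lost with the scanner software's log ratios, and those of VND6 and KCS2 without the filter on dim probes.

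**Figure D3:**
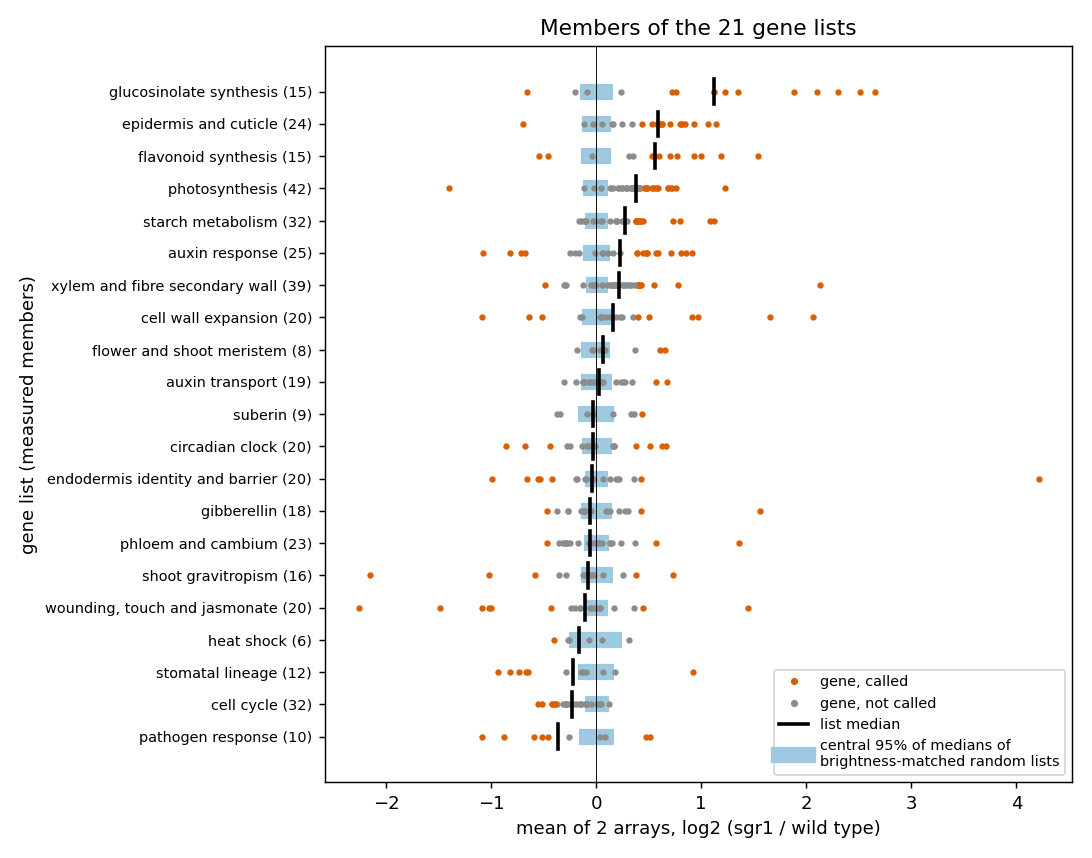
Log2 ratio of sgr1 over wild type, as the mean of the arrays, for each measured member (points, orange where called) of the 21 gene lists, with the list median as a black bar and the central 95% of medians of 10000 brightness-matched random lists as a blue band. Glucosinolate genes have the highest median (1.13).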

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

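Of the tests in this part, the count of opposite-sign genes, the comparison of epidermis with phloem genes and the comparison of list percentiles for a later stage were chosen after the result was seen. The other comparisons with brightness-matched lists were added after the data were seen, but before their own values were.

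Probes that name no locus lie outside the comparison. Of 11240 such probes without outlier flags, 3983 were well above background in at least 1 channel on each array, and 2 were at least 2-fold apart in the same direction on both arrays, both higher in sgr1. None was 2-fold apart in opposite directions, and none of 153 negative control spots met the rule.

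Of the 375 genes at least 2-fold apart on array 1 and the 481 on array 2, 291 were so in the same direction on both. A gene-specific dye bias turns sign with the dyes, so it cannot by itself give the 291 genes, which were picked for the same direction. Only 1 gene was 2-fold apart in opposite directions on both arrays, so a dye bias of that size was rare. That both arrays carry the same RNA extracts stays open, as does the cause of the photosynthesis list differing between them (median -0.0039 and 0.84), for which a dye bias and a difference between samples were not separated. Genes of the heat shock, wounding, pathogen and clock lists, which vary between plant pools, differed between the arrays in brightness no more than other genes (percentile 50.3 among brightness-matched lists) and in ratio at percentile 7.9. With a technical dye swap the p-values may describe 1 pair of extracts only.

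The rise of the epidermis and cuticle list was weighed against 3 explanations. A bias left by the normalization that depends on brightness is argued against, since the list median lay above all 10000 brightness-matched lists (percentile 100). A smaller endodermis would raise every other cell type alike, but the epidermis list exceeded the phloem list by 0.49 on the log2 scale (permutation p = 0.00025, two-sided). The permutation shuffled genes, which are not independent replicates, and was chosen after the epidermis list had been seen to rise. Its p-value therefore cannot decide on the share of cells, although the 2 lists did not rise alike on these arrays. Sampling of sgr1 segments at a later stage of development stays open: the secondary wall list lay at percentile 99.98, the stomatal list at 0.95 and the cell cycle list at 0, as a later stage would need. An effect of the sgr1 genotype on the epidermis also stays open, untested.

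Of the 100 tested genes nearest to SCR in gene order, 1 was at least 2-fold apart on both arrays, against a median of 1 in windows of that size, which argues against linked variants as a source of many changes there.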

How the results depend on the processing

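The test against 1.5-fold and the brightness-matched lists were added after the data were seen, but before their own values were. None of the 89 named genes turned its direction in a setting that gave it a value; with both channels required above background 83 had one. Scale normalization, no background correction and a normexp offset of 16 kept at least 94.1% of the calls. Aquantile normalization leaves the log ratios as they are, so that its equal result was fixed beforehand. Median centring left 2 calls (1 higher, 1 lower), 115 genes 2-fold apart on both arrays (46 higher, 69 lower), a SCR ratio of -0.98 that was no longer called, and ended 87 of the 89 named calls. The mean of SCR was nearly that with loess (-0.99), so a wider spread between the arrays ended its call, not a smaller change. The cause of that spread and of the other losses was not tested. The software's log ratio, and the series table that equals it, gave 1952 calls (999 higher, 953 lower), 45.6% of the main calls among them, 705 genes 2-fold apart (332 higher, 373 lower) and lost 16 named calls; the cause was not tested. The size rule on both arrays left 291 calls, and the test against 1.5-fold 332. Single arrays allow no test: counts of 2-fold genes were 375 to 481 (199 to 275 higher, 176 to 206 lower), and list medians ran from -0.0039 to 0.84 for photosynthesis and from -0.24 to 0.012 for wounding. Medians also differed in sign between arrays 1 and 2 for the gibberellin (-0.0063 and 0.029), suberin (0.076 and -0.019) and auxin transport (-0.0001 and 0.054) lists, which camera did not call. The averaged arrays gave 377 genes 2-fold apart, with no test. With an estimated correlation 0 lists passed, as the 1 residual degree of freedom leaves that test almost no power. Fry passed 0 lists. It rests on the same 1 residual degree of freedom, so this says little for or against any list. Camera's direction turned, without a call, for the endodermis (median -0.061) and phloem (-0.074) lists at offset 16, for endodermis (-0.074), phloem (-0.019) and clock (-0.022) with median centring, for gibberellin (-0.061) and suberin (-0.066) with the software's log ratio or the series table, and for gibberellin (-0.047) and clock (-0.012) without the dim filter; the cause was not tested. A separate-channel fit was not run, since genotype and dye terms use up both ratios of a gene and leave 0 residual degrees of freedom. Both genotypes share each array, so the test of the ratio against 0 is already a paired analysis. Signal over background limits dim genes, whose changes are understated.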

Other observations

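The gene groups in this part were drawn up after some of their members had been noticed among the strongly changed genes. The tests used only further members whose values had not been seen, and were fixed before those values were looked at. Only measured members entered the tests, and every group also held listed genes without a value.

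Genes induced by low oxygen were lower in sgr1. PCO1 (-1.85), PCO2 (-1.84), LBD41 (-1.63), HUP54 (-2.54) and FTM1 had been noticed. Of 12 further genes 8 were called lower and none higher, with a median of -0.67, among them HRA1 (-1.63), a regulator of the response, ADH1 (-0.88), alcohol dehydrogenase, and PGB1 (-0.90), a phytoglobin. The median lay below all 10000 brightness-matched lists (percentile 0). A candidate explanation is a weaker low oxygen response in sgr1 stems at harvest. Genes responding to salicylic acid were lower as well. After PCC1, LURP1 (-2.03), NIMIN1 (-1.72) and WRKY53 had been noticed, 8 of 11 further genes were called lower and none higher (median -0.74, percentile 0). These included PNP-A (-1.41), NIMIN2 (-1.40), WRKY54 (-1.28) and SARD1 (-1.29), a regulator of salicylic acid synthesis. A weaker salicylic acid response may account for them and for PR5 and WRKY70, but PR1, a standard marker of that response, did not pass (0.04) and EDS5 rose (0.51), so the explanation covers only part of the pathway.

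Iron deficiency genes were higher in sgr1. IMA1 (1.97) and IMA2 (2.14), iron-signalling peptides with similar sequences, and FSD1 (1.96), an iron superoxide dismutase, had been noticed. Of 12 further genes only 6 were measured, and BHLH38, BHLH39, BHLH100, BHLH101, IRT1 and IMA3 had no value. Of the 6, 3 were called higher, FRO3 (0.73), OPT3 (0.66) and PYE (0.54), and NAS4 was called lower (-0.43). BTS (-0.19) and FRO2 (0.28) were not called. The median of the 6 lay at percentile 99.79. FSD1 is known to be lowered, not raised, when iron is short, so an iron deficiency response may hold for only part of the group. Genes of abscisic acid and dehydration responses were higher too. RAB18, COR15B (1.86), LTP3 (2.08) and CYP707A2 (2.07) had been noticed, and of 15 further genes 7 were called higher and 1 lower (median 0.35, percentile 99.96). LTP4 (1.28) and COR15A (0.70) are close copies of noticed genes and may share their probes' signal, while RD29A (0.62) and HAI2 (0.52) rose and HAI1 fell (-0.69). A stronger abscisic acid response is a hypothesis that these values leave open.

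The glucosinolate rise may be larger in the aliphatic branch. Among further genes outside the fixed list, all 4 counted as aliphatic were called higher, such as FMOGS-OX3 (1.51) and GSTU20 (0.88). Of 5 counted as indolic, 1 was called higher, GGP1 (0.62), and 1 lower, CYP81F2 (-0.60). The branches differed by 0.85 on the log2 scale (exact permutation p = 0.0238, two-sided, 126 splits). The permutation shuffled genes, which are not independent replicates. APK1, counted as aliphatic, supplies sulfate donors to both branches. GGP1, counted as indolic, is likewise not particular to its branch, so the split is not clean. CYP79B3, an entry enzyme of the indolic branch in the fixed list, also rose (1.12), but was singled out after its value was seen. CYP83B1, of the same branch and list, fell. The rise of CYP79B3 thus does not by itself show a rise of the indolic branch.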
